A study of Drosophila melanogaster with 3 samples.

How the data were processed

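The labels describe 3 biological replicates of whole mixed-sex embryos, 4 to 16 h old, from a fly line with a transgene for GFP-tagged nerfin-1. Per the labels, chromatin was sonicated, fragments were 200 to 800 bp long and the precipitation used an antibody against GFP. All 3 replicates form 1 group. Another label gives the age as a number of hours too large for an embryo, and the range above was taken from the sample source label. The submitters deposited peak lists on the dm6 build in narrowPeak form, 1 for each replicate, 1 for the pooled replicates and 1 thresholded by IDR. Per the file headers, each list was called against a control file, which was not used here. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The signal values of the peaks (column 7) are those the authors deposited, with no normalization stated, and they were used only to order peaks within a list, to correlate ranks across matched peaks and with G+C content, and to draw the region of nerfin-1. The −log10 q-values that the authors deposited (column 9) reached their maximum in 100% of the IDR list and 26.1% of the pooled list, so they were not used to order peaks. Replicate and pooled lists all had 30000 rows, a sign of a limit on their number, and the peak lists give no read counts, so depth per replicate is unknown and no precision could be set from it. Several summits can share 1 peak interval, as 423 rows of the IDR list did, and each summit was treated as a separate site.

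Genes and TSSs came from the Ensembl release 115 annotation of BDGP6.54 and sequence from RefSeq release 6, which has the coordinates of dm6, on the 6 arms 2L, 2R, 3L, 3R, 4 and X. Pseudogenes and transposable elements were left out. Each replicate was reduced to its 7056 strongest peaks, the size of the IDR list, and summits within 100 bp of each other were counted as shared. Chance came from 1000 placements of the summits at random positions of the same arm. A summit within 500 bp of a TSS was a promoter summit, then came coding exon, other exon, intron and intergenic sequence in that order. Random positions included stretches where reads cannot be placed uniquely. A separate setting limited them to the span of the pooled summits on each arm, which kept such stretches within the span.

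Each IDR summit went to the protein-coding gene with the nearest TSS. The number of genes of a list with a summit was set against 10000 random lists, each member drawn from the 200 genes closest to it in territory, with two-sided permutation p values (the smallest possible is 2e-04) and Benjamini-Hochberg adjustment over the 21 lists. Members of a random list were drawn independently, so genes of a list that lie side by side were counted as independent. Assignment to the nearest TSS does not show which gene a site regulates. Of 334 genes listed by symbol, 334 were matched, 7 of them by an older symbol. Aliases for renamed genes were added after the annotation was seen, and no gene was added or removed. Each of 14 words was sought on both strands within 50 bp of the summit and in a 100-bp window centred 400 bp to a randomly drawn side, with an exact McNemar test and Benjamini-Hochberg adjustment over the 14 words; p values of lists and words are over genes and summits, not over replicates. Gene lists and words were fixed before the data were examined. Genes were named by a rule fixed at the same time. It took the genes nearest to the 10 strongest IDR summits, the 10 genes with the most summits, the 4 best-ranked members and up to 2 members without a summit of each list past 0.05, the 2 best-ranked members of every other list, and always nerfin-1, dpn, Myc and N. Genes beside nerfin-1 were named after their values were seen, and 1 gene that the rule takes is not reported here.

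The tests of lists, words and location were tested on simulated data. With the IDR summits at random positions, 4.5% of 200 random lists and 4% of 50 lists of genes with long territories had p under 0.05, and 20 of 20 lists with summits planted at 15 of 30 genes were called above chance. The simulated summits, apart from planted ones, were spread evenly over each arm, whereas the real ones gathered at promoters and at some genes. The simulation therefore does not show that matching on territory suffices for the real lists. A word planted at 20% of 398 summits in random sequence was recovered, at an excess larger than that of any word at IDR summits. Of the 5 location classes of randomly placed summits, 1 had an unadjusted and 0 an adjusted p under 0.05. Base composition was the G+C share of the 200 bp around a summit. Alternatives changed the distance that counts as shared, the promoter width, the rule that assigns summits to genes, the background, the word window, the strength limit and the replicates. Without a replicate, lists, words, location and nerfin-1 were recomputed on the IDR summits matched within 100 bp among the strongest peaks of both other replicates (3701, 4654 and 3947 summits without replicates 1, 2 and 3), so the list, called on all replicates, was filtered and not called again. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.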

Results

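Binding of Nerfin-1, a zinc-finger transcription factor of newly born neurons and a relative of vertebrate INSM1, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster embryos. The flies carried a transgene that makes the protein with green fluorescent protein (GFP) at its C terminus, and an antibody against GFP pulled down the chromatin. Whole embryos of both sexes, collected 4 to 16 h after laying, gave 3 biological replicates of 1 group, so the comparisons are between replicates and with chance. The values analysed were peak lists on the dm6 build. Each replicate list held 30000 peaks, as did the list called on the pooled replicates, and a list thresholded by the irreproducible discovery rate (IDR) held 7056. Read depth is unknown from these lists, and the intervals below cover counting error over summits only. The 7056 peaks of the IDR list were the 7056 strongest of the pooled list, row for row, so that list was a limit on pooled signal and did not require each peak in each replicate.

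The strongest Nerfin-1 sites were found in every replicate, and the weakest of the list seldom were. The strongest summit lay at position 20401813 of arm 3L (peak 20401302 to 20402180), 204 bp from a transcription start site (TSS) of trbl (FBgn0028978), which encodes the Tribbles pseudokinase that restrains cell division. It ranked 1 in replicate 1, 20 in replicate 2 and 1 in replicate 3. Next came dup, which encodes the replication licensing factor Cdt1, with a summit at 15378809 of arm 2R in an intron, and klu, a zinc-finger gene of neural stem cells (neuroblasts), with a summit at 11010484 of arm 3L, 1296 bp from a TSS. The rest of the 10 strongest summits lay nearest to RpS10a, CG14100, Ugalt (a UDP-galactose transporter), msps (a microtubule polymerase), chn (a zinc-finger repressor of the nervous system), CG7304 and mRpL41 (a mitochondrial ribosomal protein). Replicate 2 ordered these sites differently. Its 3 strongest of them were the promoter summits of CG14100, mRpL41 and Ugalt, at ranks 1, 2 and 3, which ranked 46, 83 and 29 in replicate 1 and 44, 94 and 38 in replicate 3, whereas chn ranked 5, 141 and 5 in replicates 1, 2 and 3.

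Across the IDR list, 75.3% ± 2.56 (SD, n = 3) of summits had a summit within 100 bp among the 7056 strongest peaks of a replicate, against 1.07% for random positions on the same chromosome arm. The shares were 78.2% in replicate 1 (Wilson 95% interval 77.2 to 79.2), 73.8% in replicate 2 (72.8 to 74.8) and 73.7% in replicate 3 (72.7 to 74.8). The IDR list is the top of the list pooled from these replicates, so its summits were bound to recur in them more often than random positions. Directly between replicates, 72.8% of the 7056 strongest summits of replicate 1 had one within 100 bp in replicate 3 and 56.3% in replicate 2. Of those of replicate 2, 52.3% had one in replicate 3. The mean was 60.5% ± 10.9 (SD over 3 pairs), against 1.06% at random (two-sided permutation p = 0.002 for each pair, the smallest that 1000 placements can give). Random positions were not matched to summits on promoter location or open chromatin. This p therefore shows only more sharing than at uniformly spread positions. Among their 7056 strongest peaks, all 3 replicates held 3338 summits (47.3%, Wilson 95% interval 46.1 to 48.5). There 2 replicates held 2288, 1 replicate held 1341, and no replicate held 89. The share was 98.9% ± 0.283 (SD, n = 3) in the decile of summits with the highest signal and 44.3% ± 2.60 in the decile with the lowest. All 3 replicates held 97.2% of the summits of the first and 0.567% of those of the last. The last decile lies next to the limit of 7056 peaks set for each replicate, so part of the fall follows from that limit. Against all 30000 peaks of a replicate, the share of IDR summits matched was 93.0% ± 1.20 (SD, n = 3). It is not given by decile here, so how often the weakest summits were called at all is not shown.

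**Figure D1:**
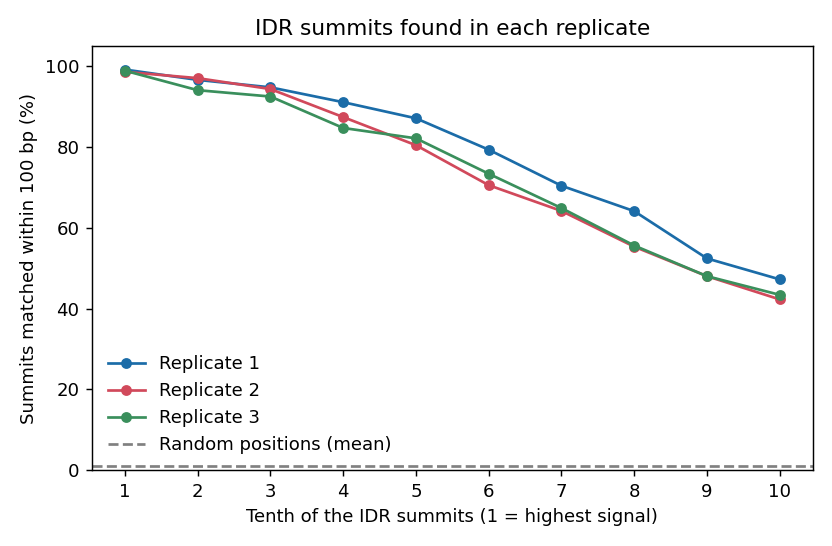
Percentage of IDR summits with a summit within 100 bp among the 7056 strongest peaks of each replicate (y axis), by decile of the IDR list from highest to lowest signal (x axis). Lines are the 3 replicates and the dashed line is the mean for random positions; the mean over replicates goes from 98.9% in the first decile to 44.3% in the last.

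Replicate 2 stood apart in the order of its peaks and in the sequence beneath them. Across IDR summits found in both lists, Spearman's rho of the deposited signal was 0.825 between replicates 1 and 3 (6240 summits), 0.443 between 1 and 2 (6174 summits) and 0.373 between 2 and 3 (6028 summits), with a mean of 0.547 ± 0.243 (SD over 3 pairs). These correlations are across peaks, which are not independent replicates. The 200 bp around the 7056 strongest summits held 36.5% G+C in replicate 2, 42.0% in replicate 1 and 42.4% in replicate 3, and 42.1% around random positions. Signal and G+C content correlated negatively across IDR summits in replicate 2 (rho = -0.455) and positively in replicate 1 (rho = 0.188) and replicate 3 (rho = 0.240).

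The summits were frequent at promoters and rare in coding sequence. Of the 7056 IDR summits, 3535 (50.1%) lay within 500 bp of a TSS, 3.73 times the 13.4% of random positions on the same arms. The share among the strongest peaks of single replicates was 50.1% ± 0.716 (SD, n = 3), and 1554 IDR summits lay within 100 bp of a TSS. Coding exons held 32 summits (0.453% against 13.9% at random), other exons 173 (2.45% against 5.75%), introns 2314 (32.8% against 39.3%) and intergenic sequence 1002 (14.2% against 27.7%). Each of these 5 classes differed from 1000 random placements, with an adjusted p of 0.002 by the permutation test. The weaker summits of the pooled list lay at promoters in 26.7% of cases, against which the ratio for the IDR list was 1.87.

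A few genes gathered many summits each. The nearest-TSS rule gave 3986 of 13945 protein-coding genes (28.6%) at least 1 summit, 2630 of them exactly 1, and 238 genes 5 or more. The genes with the most were tara and Eip75B with 19 each, Tlk and tna with 17 each, px and shn with 15 each, sbb, hth and CG15233 with 14 each, and apt with 13. Of these, Eip75B encodes an ecdysone-induced nuclear receptor, shn a zinc-finger protein and hth a homeodomain protein. The counts were not adjusted for the length of a gene's territory.

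Genes of neural stem cells, their temporal series, neuron identity and axon guidance held summits more often than genes with equally long surroundings. Summits were found at 15 of 18 neuroblast genes (7.42 by chance), 16 of 18 temporal factors (8.73 by chance), 29 of 34 neuron identity factors (15.9 by chance) and 31 of 37 axon guidance genes (17.0 by chance). Chance was the mean of 10000 random lists matched on territory, the sequence nearer to a gene's TSS than to any other. The two-sided permutation tests gave adjusted p values, by Benjamini-Hochberg over 21 lists, of 0.00158 for neuroblast genes, 0.00233 for temporal factors and 7.00e-04 for the other 2 lists. The numbers in single replicates were 14.7 ± 2.31, 16.0 ± 0, 27.3 ± 3.79 and 29.7 ± 1.15 (SD, n = 3) in that order, and replicate 2 held 12 neuroblast genes where replicates 1 and 3 held 16 each.

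The best-ranked neuroblast genes were klu (rank 3), SoxN (rank 50), aPKC (rank 80) and baz (rank 186), the last 2 of which encode cell polarity proteins. The neuroblast genes dpn and nab had no IDR summit. Among temporal factors, which succeed each other in ageing neuroblasts, cas ranked 154, chinmo 258, slp2 378 and tll 420, while hb and mamo had none. The strongest neuron identity factors were the homeobox genes vvl (rank 387), zfh2 (rank 399), Lim1 (rank 792) and the Pax6 gene toy (rank 932), and eg and fru had none. The axon guidance genes Dscam1 (rank 253), Lar (rank 296), fra (rank 538) and drl (rank 555) encode cell-surface receptors, and beat-Ia and Eph had none. By contrast, genes of mature neuron function were not above chance, with summits at 11 of 28 (11.05 expected, adjusted permutation p = 1), although brp, an active zone protein gene, ranked 79 and elav, the pan-neuronal RNA-binding protein gene, ranked 140. Proneural genes had summits at 5 of 10 (3.76 by chance, adjusted permutation p = 0.728), with tap at rank 777 and l(1)sc at rank 1906.

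Genes of the Notch and Hippo pathways and of the cell cycle were also above chance. Notch pathway genes had summits at 18 of 24 (7.85 by chance, adjusted p = 7.00e-04; 17.7 ± 1.15 in single replicates, SD, n = 3, permutation test). They were led by mib1, a ubiquitin ligase for Notch ligands (rank 32), numb, an inhibitor of Notch (rank 200), and the E(spl) complex genes E(spl)mgamma-HLH (rank 220) and E(spl)m3-HLH (rank 338), while BobA and E(spl)m5-HLH had none. The receptor gene N had 1 summit (rank 4449). Many members of the Notch list lie side by side in the E(spl) complex. The random lists did not keep neighbours together, so the p of this list counts them as independent. Hippo pathway genes had summits at 11 of 13 (4.54 by chance, adjusted p = 0.00158; 11.3 ± 0.577, SD, n = 3, permutation test), with the coactivator gene yki at rank 28, its DNA-binding partner sd at rank 373, the caspase inhibitor gene Diap1 at rank 448 and kibra at rank 1751, and none at sav and vg. Cell cycle genes had summits at 14 of 20 (5.73 by chance, adjusted p = 7.00e-04; 14.3 ± 1.53, SD, n = 3, permutation test), with trbl and dup at ranks 1 and 2, CycB at 104 and CycA at 914, and none at Cdk1 and Cdk2.

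Part of these list results depended on the background. When genes were matched on their number of weaker pooled summits in place of territory, 3 lists were no longer past the threshold: neuroblast genes (11.8 by chance, ratio 1.27, adjusted permutation p = 0.275), temporal factors (11.9 by chance, ratio 1.35, adjusted permutation p = 0.103) and axon guidance genes (26.5 by chance, ratio 1.17, adjusted permutation p = 0.193). Neuron identity factors (ratio 1.33, adjusted permutation p = 0.0116), Notch (1.51, 0.0434), Hippo (1.82, 0.0193) and cell cycle genes (1.82, 0.0116) stayed above chance there. Counts of weaker summits have many ties (7942 of 13945 genes had none), and ties were ordered by gene identifier. Within a tie, random members came from genes with nearby identifiers, so this setting does not isolate weak peaks. Counts of TSSs, used below, tie in the same way. Settings without a replicate used, for lists, words and nerfin-1, the IDR summits found in both other replicates, which is a stricter and shorter list. Without replicate 3 (3947 summits in both replicates 1 and 2) the neuroblast list was not past it (ratio 1.86, adjusted permutation p = 0.0764). Counting only summits within 1000 bp of a TSS, with genes matched on their number of TSSs in place of territory, took the neuroblast (adjusted permutation p = 0.210), temporal (0.210), neuron identity (0.609) and cell cycle (0.0947) lists below it, as did gene bodies, matched on their length, for the neuroblast (0.0852), Hippo (0.274) and cell cycle (0.176) lists and the stronger 3528 summits for neuron identity (0.373).

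Ribosomal protein genes had the largest excess among the 21 lists by ratio to chance. Summits were found at 74 of 92 (22.7 by chance, 3.27-fold, adjusted p = 7.00e-04, permutation test), and at 74.0 ± 2.00 (SD, n = 3) in single replicates. Of the 83 summits assigned to these genes, 80 lay at promoters. RpS10a ranked 4, RpS27 441 and RpL34b 525, and RpL10 and RpL10Aa had none. The ratio of a list cannot exceed its size over the number expected. That limit is below 3.27 for the neuroblast, temporal, neuron identity, axon guidance, Notch and Hippo lists, so they could not have reached the ribosomal ratio. Odorant and gustatory receptor genes were below chance, with summits at 9 of 119 (34.2 by chance, 0.263-fold, adjusted p = 7.00e-04, permutation test) and at 8.67 ± 1.15 (SD, n = 3) in single replicates. The best-ranked were Or67d (rank 1482), Gr93a (1670), Gr93d (1821) and Gr89a (2568), and Gr10a and Gr10b had none. With distal summits alone the ratio of this list was 0.601 (adjusted permutation p = 0.162).

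**Figure D2:**
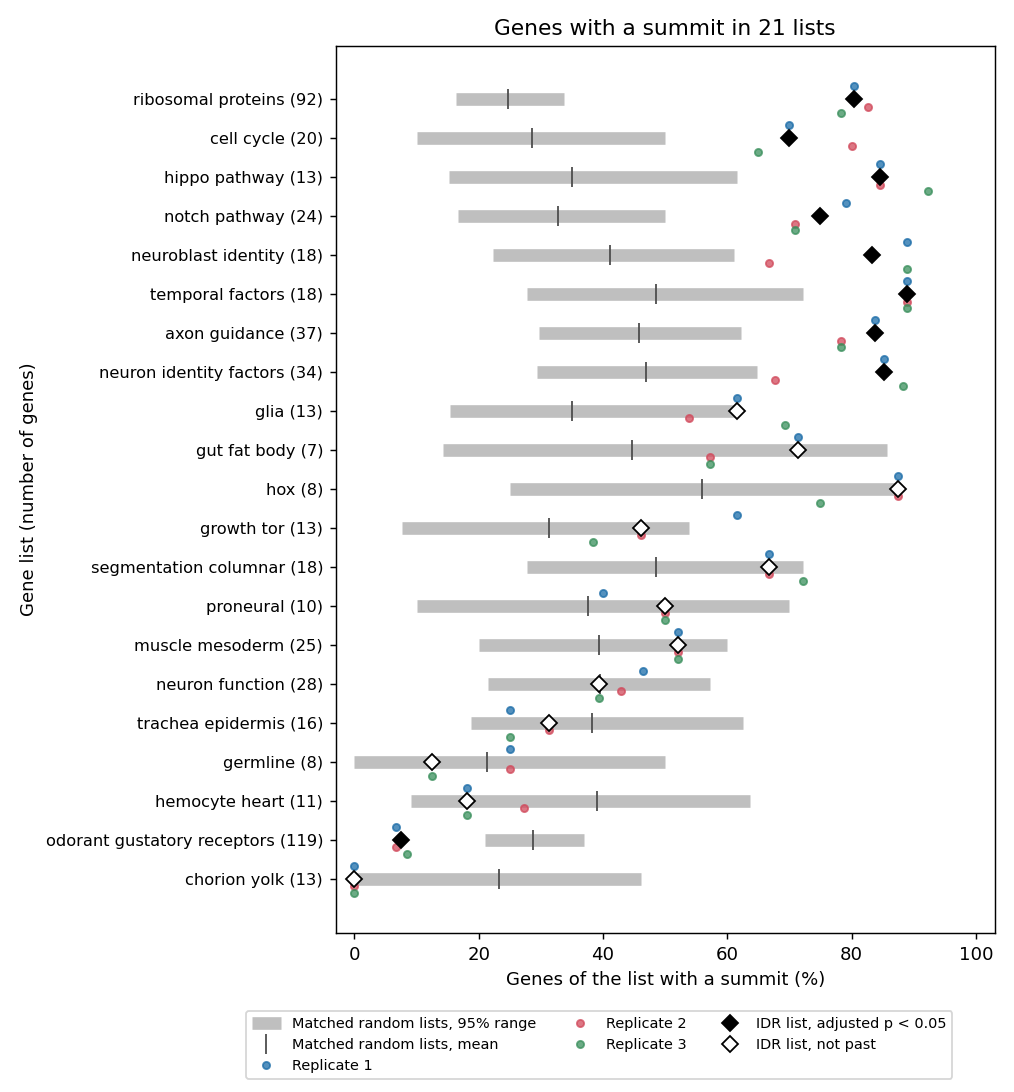
Percentage of the genes of each list with an assigned summit (x axis), for 21 lists with their number of genes (y axis). Diamonds are the IDR list, filled where the adjusted p was under 0.05, coloured points are the 7056 strongest peaks of each replicate, grey bars are the range of 95% of 10000 matched random lists and ticks their mean; 8 lists lie above their grey bar with a filled diamond and 1 lies below it.

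The lists of other cell types of the embryo, and those of Hox, patterning, growth and ovary genes, did not pass the test in either direction. Several of these lists are short, which limits the test. The ovary list held the lowest possible count and so could not have passed below chance. The ratios of glial (1.76), gut (1.60) and Hox genes (1.56) were not far below the 1.82 of neuron identity factors. Summits were found at 8 of 13 glial genes (4.56 by chance, adjusted permutation p = 0.153), led by nrv2 (rank 99) and the glial homeobox gene repo (rank 233). The glial list was above chance with the stronger 3528 summits (8 against 2.79 by chance, ratio 2.86, adjusted permutation p = 0.0078) and without replicate 2 (ratio 2.29, adjusted permutation p = 0.0214). Summits were found at 13 of 25 muscle and mesoderm genes (9.85 by chance, adjusted permutation p = 0.378), led by Mef2 (rank 44) and tin (rank 146). Gut and fat body genes had summits at 5 of 7 (3.13 by chance, adjusted permutation p = 0.386; fkh at rank 790, dve at 1729), and trachea and epidermis genes at 5 of 16 (6.11 by chance, adjusted permutation p = 0.839; trh at 1045, rib at 1336). Blood and heart genes had them at 2 of 11 (4.30 by chance, adjusted permutation p = 0.374; ush at 680, crq at 1869), and germ cell genes at 1 of 8 (1.70 by chance, adjusted permutation p = 0.966), which was bgcn at rank 1396. Hox genes had summits at 7 of 8 (4.48 by chance, adjusted permutation p = 0.230), with Ubx at rank 12 and abd-A at rank 39, and segmentation and columnar patterning genes at 12 of 18 (8.73 by chance, adjusted permutation p = 0.291), with H15 at rank 11 and en at rank 689. Insulin and TOR growth genes had them at 6 of 13 (4.07 by chance, adjusted permutation p = 0.450), with InR at rank 232 and path at rank 2256. The growth regulator gene Myc, which was always to be named, had 5 summits, the best at rank 1839. Eggshell and yolk genes of the adult ovary had summits at 0 of 13 (3.03 by chance, adjusted permutation p = 0.135). By Fisher's exact test without matching on territory, the glial (exact adjusted p = 0.0224), muscle (0.0224), gut (0.0349), Hox (0.00178) and patterning lists (0.00178) were above the share of all genes and the ovary list (0.0363) below it.

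Among 14 sequence words fixed before the data were examined, the Scalloped (TEAD) word RCATTCC was the one enriched at summits with the smallest p. It occurred within 50 bp of 355 of 7056 summits (5.03%) and in 157 windows of equal size centred 400 bp to the side (2.22%), a ratio of 2.26 (adjusted p = 3.57e-18, exact McNemar test over summits). In single replicates it was at 4.92% ± 1.03 of summits and in 2.06% ± 0.107 of flanks (SD, n = 3). The DREF word TATCGATA was at 1.52% of summits and in 0.425% of flanks (ratio 3.57, exact adjusted p = 1.70e-10), and over distal summits alone at 0.1704% and 0.1136% (exact adjusted p = 0.851). It was at 2.10% of the strongest summits of replicate 2, 1.32% of replicate 1 and 1.13% of replicate 3, and without replicate 2 its ratio was 2.31 (exact adjusted p = 0.00124). The Mef2 word YTAWWWWTAR was at 5.12% and 3.43% (ratio 1.49, exact adjusted p = 2.64e-06). In single replicates the excess was largest in replicate 2, with 6.79% of summits and 2.93% of flanks, against 3.93% and 3.70% in replicate 1 and 3.76% and 3.33% in replicate 3, and without replicate 2 the ratio was 1.40 (exact adjusted p = 0.00527). The Snail-family E-box CAGGTG was rarer at summits than in flanks (2.21% and 3.88%, ratio 0.569, exact adjusted p = 3.04e-08).

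The homeodomain word TAATTA was at 7.47% of summits and in 6.18% of flanks (ratio 1.21, exact adjusted p = 0.00805), and this call rested on replicate 2, the replicate with the lowest G+C content. It was at 9.57% of the strongest summits of replicate 2, 5.58% of replicate 1 and 5.67% of replicate 3, and without replicate 2 the ratio was 0.969 (exact adjusted p = 0.828). Within 25 bp of the IDR summits the ratio was 1.14 (exact adjusted p = 0.334). Conversely, the GAGA word GAGAG was at 13.7% of summits and in 13.1% of flanks (ratio 1.04, exact adjusted p = 0.444). Single replicates went in opposite directions, with 16.5% of summits and 13.4% of flanks in replicate 1, 17.4% and 12.7% in replicate 3, but 10.5% and 14.7% in replicate 2. The GAGA word passed without replicate 2 (15.4% and 12.8%, ratio 1.21, exact adjusted p = 0.00124) and against random positions of the same arm and promoter class (ratio 1.20, exact adjusted p = 1.32e-04). The INSM1-like word YWGGGGG was not enriched, at 2.34% of summits and in 2.89% of flanks (ratio 0.809, exact adjusted p = 0.0907). It was below the flank without replicate 1 (ratio 0.604, exact adjusted p = 0.00324), without replicate 3 (ratio 0.558, exact adjusted p = 3.83e-04), within 25 bp (ratio 0.591, exact adjusted p = 0.00291) and with the stronger 3528 summits (ratio 0.598, exact adjusted p = 0.00135). It did not pass without replicate 2 (ratio 0.947, exact adjusted p = 0.828) or with distal summits (ratio 0.842, exact adjusted p = 0.594). Nor did it with promoter summits (ratio 0.719, exact adjusted p = 0.121) or against random positions (ratio 0.846, exact adjusted p = 0.196). Against the pooled list's weaker summits it was rarer (ratio 0.623, adjusted p = 1.69e-08, Fisher's exact test). In windows 130 bp to the side the ratio to the flank was 1.08 (exact adjusted p = 0.566). The INSM1-like word was at 1.33% of the strongest summits of replicate 2 against 2.66% in replicate 1 and 2.82% in replicate 3. Flanks and random positions were not matched to summits on base composition. IDR summits held 39.7% G+C and random positions 42.1%, and the G+C content of flanks was not measured. Composition was therefore not separated from the word results, among them the INSM1-like, Mef2, homeodomain, DREF and Snail-family results. The other 7 words, for Zelda, proneural and Hairy-family E-boxes, Su(H), Sox, Tramtrack and Prospero, did not pass, with ratios from 0.840 to 1.37 and exact adjusted p from 0.0774 to 0.622. Of these the Hairy-family E-box was enriched without replicate 2 (ratio 1.69, exact adjusted p = 0.00643) and against random positions of the same arm and promoter class (ratio 1.44, exact adjusted p = 0.0294).

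Some words were more frequent beside the summit than in the flank. In windows centred 130 bp to the side, a distance chosen after the positions of words around summits were seen, the GAGA word was at 18.5% against 13.1% in flanks on the same side (ratio 1.41, exact adjusted p = 5.84e-18). The proneural E-box was at 5.81% against 4.05% (ratio 1.43, exact adjusted p = 7.64e-06). The DREF word was at 1.49% against 0.3685% (ratio 4.04, exact adjusted p = 1.32e-11). The Scalloped word (ratio 1.06, exact adjusted p = 0.693), the Mef2 word (ratio 0.930, exact adjusted p = 0.566), the homeodomain word (ratio 0.864, exact adjusted p = 0.0979) and the Snail-family E-box (ratio 0.817, exact adjusted p = 0.0896) did not pass in these windows.

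**Figure D3:**
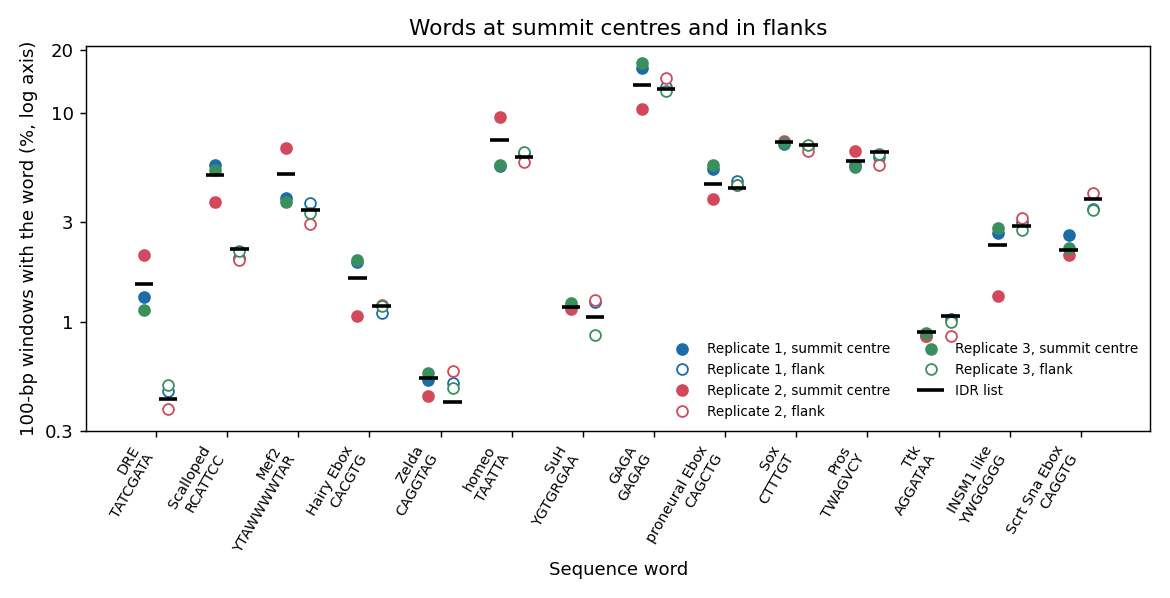
Percentage of 100-bp windows with each of 14 words (y axis, log scale), by word in order of the ratio of summit to flank (x axis). Filled points are windows centred on the 7056 strongest summits of each replicate, open points are flank windows 400 bp to the side, and black bars are the IDR list; the Scalloped word is at 5.03% of IDR summits and in 2.22% of flanks, and the homeodomain word is at 9.57% of summits in replicate 2.

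The nerfin-1 gene itself (FBgn0028999, arm 3L, 909112 to 912319) was within a dense group of sites. The IDR list had 4 summits nearest to its TSS, at 907902 and 908108 upstream and at 908984 and 909203 in the promoter, with ranks 822, 1335, 475 and 4222. All 4 shared 1 peak interval, 907249 to 909608. The strongest peaks of replicates 1, 2 and 3 held 4, 2 and 3 summits of nerfin-1 (mean 3.00 ± 1.00, SD, n = 3). Of the 4 IDR summits, 3 had a match within 100 bp among these peaks in both replicates 1 and 3. In both replicates 1 and 2 it was 1 summit, and in both replicates 2 and 3 it was 0. The 20 kb either side of the gene held 19 IDR summits, of which 15 lay nearest to other genes, and the strongest was near CG34057 at 899462 (rank 24). The pooled list had 19 summits 5 to 20 kb from the gene, more than in the same windows of 94.1% of 13945 genes. Of 4465 windows of 30 kb, the one from 900001 to 930000 had the most IDR summits, 16, against a median of 1. The next densest window, on arm 2R, had 14, and further windows on other arms had 13.

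**Figure D4:**
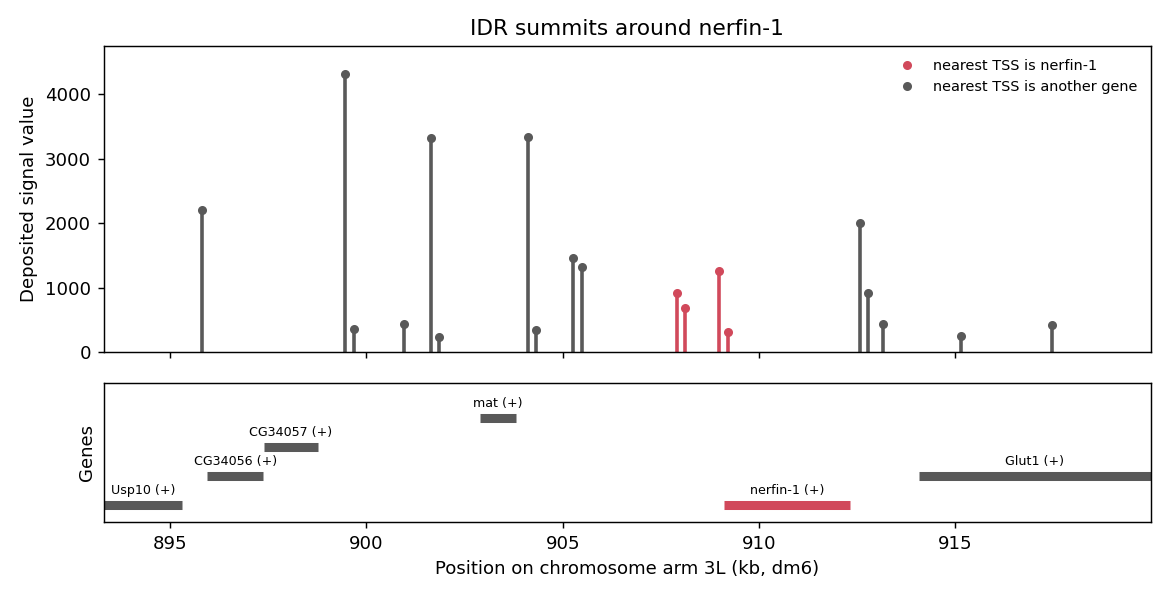
Signal value deposited for each IDR summit (upper panel, y axis) and protein-coding genes (lower panel) along arm 3L in kb (x axis, dm6). Red marks the 4 summits nearest to the TSS of nerfin-1 and the gene itself, and grey marks the other 15 summits of the region and the other genes, with the highest signal near CG34057.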

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

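The alternatives with any pooled summit, with all genes matched on weaker summits, with pairs of replicates, with weaker summits as background, with distal or promoter summits only, with summits near nerfin-1 left out, with word windows beside the summit, with placements limited to the pooled span and with ranks regressed on G+C content were chosen after the data were seen. Sharing between replicates and the 5 location classes kept their direction and their side of the threshold under every alternative run. Using the strongest peaks of the pooled list in place of the IDR list gave the same peaks, so that choice, planned beforehand, tested nothing and has no value. In all, 445 alternative values were the same by direction and threshold or stayed within the spread, 19 passed the threshold newly, 31 fell below it, 18 moved further and 5 reversed. Read depth is unknown, so its limits could not be set.

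The 8 lists above chance became 4 with summits within 1000 bp of a TSS and matching on the number of TSSs, 5 with gene bodies and 2000 bp around them and matching on that length, 13 with Fisher's exact test without matching, 5 with all genes matched on weaker summits and 1 among genes with any pooled summit. The 1 list below chance became 2 with Fisher's exact test, 0 among genes with any pooled summit and 0 with distal summits only. With summits within 1000 bp of a TSS, the ratios no longer past the threshold were 1.55 for neuroblast, 1.42 for temporal, 1.19 for neuron identity and 1.65 for cell cycle genes. With gene bodies they were 1.46 for neuroblast, 1.39 for Hippo and 1.47 for cell cycle genes. With all genes matched on weaker summits they were 1.27 for neuroblast, 1.35 for temporal and 1.17 for axon guidance genes. Genes with any pooled summit are chosen partly by the IDR summits themselves, so their values say nothing about stability: they were 1.28 for neuroblast, 1.47 for Notch, 1.34 for temporal, 1.18 for axon guidance, 1.25 for neuron identity, 1.36 for Hippo, 1.22 for cell cycle and 0.877 for receptor genes. Counting summits gave 1.86 for temporal and 1.53 for neuron identity genes. The stronger 3528 IDR summits gave 1.36 and promoter summits 1.17 for neuron identity genes, and promoter summits gave 2.11 for cell cycle genes. Distal summits gave 0.601 for receptor genes and 0.446, a reversal, for ribosomal protein genes, whose summits were nearly all at promoters and so were left out. Apart from that, the cause was not tested, and the TSS and gene body settings changed both assignment and matching.

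Settings without a replicate kept, except for sharing and rank correlation, the IDR summits found in both others, so they mix the omission with a stricter, shorter list. They moved the mean rank correlation between 0.373 (without replicate 1) and 0.825 (without replicate 2), the neuroblast ratio between 1.86 (without replicate 3) and 2.33, the homeodomain ratio between 0.969 (without replicate 2) and 1.43, the words below the flank between 1 and 2, and the nerfin-1 summits between 0 (without replicate 1) and 3. With ranks regressed on G+C content the correlations were 0.606 for replicates 1 and 2, 0.557 for 2 and 3 and 0.820 for 1 and 3. The 4 words above the flank became 2 with distal summits only, 3 within 25 bp and with promoter summits, 5 without replicate 2 and 6 against random positions. The 1 word below became 2 within 25 bp and with the stronger 3528 summits, and 3 against weaker summits, where the proneural E-box reversed to 0.865, and 0 in windows 130 bp to the side, where the homeodomain and Mef2 words reversed to 0.864 and 0.930. The causes were not tested.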

Other observations

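The tests of promoter share by list, of base composition, of lists with every gene matched on weaker summits and of the density of summits beside nerfin-1 were chosen only after the results were seen, and the settings with distal summits and with any pooled summit were added after the data were seen.

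Where the sites lay differed between gene groups. Against 50.1% of all IDR summits, the share at promoters was lower in 10 lists by Fisher's exact test of each list against all other summits, adjusted over 21 lists. It was 8.82% for Hox genes (exact adjusted p = 2.64e-06), 18.2% for neuron identity factors (7.13e-08), 16.7% for segmentation and columnar patterning genes (7.64e-04), 30% for axon guidance genes (6.12e-04) and 6.25% for odorant and gustatory receptor genes (9.25e-04). For neuron function (26.5%), glial (25%), muscle (27.3%), neuroblast (29.5%) and temporal genes (31.2%) the exact adjusted p was between 0.0167 and 0.0273. Ribosomal protein genes lay on the other side, with 96.4% of 83 summits at promoters (adjusted exact p = 2.75e-19). Their summits had a median distance of 41 bp to the nearest protein-coding TSS. These tests counted summits as independent, although several can belong to 1 gene, as 12 of the 34 Hox summits did to Antp. The tests were not matched on territory, so differences in gene spacing were not separated. Summits per Mb were 55.8 on 2L, 55.1 on 2R, 54.6 on 3L, 52.4 on 3R, 47.0 on X and 23.0 on the small arm 4, and on arm 4 the strongest peaks of single replicates gave 26.7 ± 6.80 (SD, n = 3).

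Ribosomal protein genes held IDR summits 3.27 times as often as matched genes. Summits that belong to the promoter of a neighbouring gene were tested by leaving out every gene with another protein-coding gene's TSS within 500 bp. Non-coding neighbours were not considered. The ratio was then 3.33 (42 of 55 genes against 12.6 by chance, permutation p = 2e-04, the smallest possible), which argues against protein-coding neighbours as the source. A signal that follows promoter openness, without the sequence of distal sites, stays open. The Scalloped word was at 1 of 80 promoter summits of these genes and in 0 flanks, an excess of 1.25 percentage points with a 95% interval from -2.15 to 4.59 that includes both 0 and the distal excess of 3.27, so these explanations cannot be told apart with 80 summits, and no biological explanation was tested.

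The neuroblast, Notch, temporal, axon guidance and neuron identity lists held summits more often than genes with equally long territories, whereas the neuron function, proneural and glial lists did not pass. Promoter openness alone was tested on those 5 lists, which had already passed, with distal summits. There 5 of the 5 stayed above chance (ratios 1.77 to 2.88, adjusted permutation p 0.0021 to 0.0077). This argues only against promoter summits as the sole source of the excess. Few summits of these lists were at promoters to begin with (18.2% to 33.3%). Openness of distal sites was not tested. A tendency of these genes to lie near weak peaks was tested with all genes matched on weaker summits. There 2 of the 5 stayed above chance, Notch (ratio 1.51, adjusted permutation p = 0.0434) and neuron identity (ratio 1.33, adjusted permutation p = 0.0116). That met the bound set for that explanation, fewer than 3 of the 5 lists, so part of the excess may be shared with weak peaks. Ties in the number of weaker summits were ordered by gene identifier, so the matching also followed identifiers. The test cannot separate the effects of weak peaks and of identifiers. The calls of the other 3 lists ended there because the number expected rose, from 7.42 to 11.8 for neuroblast, from 8.73 to 11.9 for temporal and from 17.0 to 26.5 for axon guidance genes, and their ratios of 1.17 to 1.35 do not show that no excess was left. The same test among genes with any pooled summit (0 of 5 lists) decides nothing, since every gene there without weaker summits holds an IDR summit, and no biological explanation was tested.

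The density of sites beside nerfin-1 may come from extra copies of the locus in the transgenic line, which could add reads if the control lacked them. The pooled list had 19 summits 5 to 20 kb from the gene, against a median of 7 for protein-coding genes. This was more than in 94.1% of 13945 genes, between the bounds of 95% for that explanation and 75% against it, which were both set after the summits there were seen, so the question stays open. The percentile was 95.6 in replicate 1, 93.6 in replicate 2, 94.1 in replicate 3 and 98.0 in the IDR list, which had 8 summits in the same windows. The extent of the transgene and the strain of the control are not given in the sources used here.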
